A study of Mus musculus with 6 samples.

How the data were processed

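The series holds 6 chromatin immunoprecipitation sequencing (ChIP-seq) samples of mouse liver, made with an antibody against Rev-erbα and taken at zeitgeber time (ZT) 10 from male mice aged 12 weeks. The labels place 3 samples in a wild-type group and 3 in an HNF6 knockout (KO) group. The processed data used here are 2 peak lists for the whole series, and neither names a sample. Per the submitters' processing notes, Bowtie and HOMER were used and coordinates refer to the mouse build mm9. Versions, the peak-calling settings, the samples that were pooled and the rule by which the second list was chosen are not given in the sources used here. Peaks were called on pooled samples according to the name of the first list, so no spread between replicates can be derived from it.

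The first list (the ZT10 list) gives chromosome, start and end of each peak, as deposited, and no score. The second list is named for independence of the DBD, the DNA-binding domain of Rev-erbα. Its peaks are called listed peaks below. It has no header, and beside the coordinates each peak carries a unique identifier, a signed distance in base pairs and 2 whole numbers. The deposited file does not label these 2 numbers, here called the first and second value, and their unit and normalization are not stated. They were treated as a score of the peak given by the authors and used to describe or rank peaks within that list. They further served to check, over the listed peaks, what the order of the ZT10 list follows. The spread of their ratio was also examined for a technical explanation under the other observations. The other ZT10 peaks carry no value, so reading their order as strength is an assumption. The distance was tested on the file itself: where 2 neighbouring peaks refer to the same point, their distances must differ by exactly their spacing. Point positions were computed as the peak centre minus the distance (plus strand) or plus the distance (minus strand), and positions shared by at least 2 peaks were kept. Negative distances are called upstream, following HOMER's convention for transcription start sites (TSS). A point position can be off by 1 bp, depending on how the centre of a peak of even width was rounded.

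Coordinates are printed 1-based in mm9. Neither an mm9 genome nor an mm9 gene annotation was used here, and the supplied gene table belongs to another build. Gene names, exon and intron annotation, the 13 sequence motifs and the 14 gene lists that had been fixed before the data were examined are therefore not analysed here. The planned tests of peak score and peak width were not made either, because the ZT10 list holds no score and all peaks share 1 width. The planned fit of wild type against HNF6 KO needs a value per sample and was not made. The rule for named sites, also fixed before the data were examined, asked for the 5 peaks with the highest score in each class and, without a score, for the 3 windows per class with the most peaks chained at under 10 kb. The first value served as the score for the listed peaks, and windows are given for both classes. Regions named outside this rule are marked as chosen after their values were seen.

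Peaks of the lists were matched at a minimum overlap of 1 bp. The planned permutation test of the overlap against circular shifts is not reported, because all listed peaks proved to be ZT10 peaks and its outcome was fixed. The order of the ZT10 list was used as a stand-in for the missing score, a choice made after seeing the data. The results on position in that list, on the upstream share, on shared points and on the 2 values were likewise set after the data had been seen. Medians of position were compared by a two-sided permutation test with 100000 resamples. Shares were compared by Fisher's exact test (two-sided) with Benjamini-Hochberg adjustment over chromosomes, and single shares carry 95% Wilson intervals. Clustering was the share of peaks with another peak of the same list within 10 kb, against 10000 random draws of as many peaks from the ZT10 list (two-sided permutation). Peaks are not biological replicates, so every interval and p-value describes these lists and covers counting error only. The sequencing depth of the samples is unknown from these files. Alternatives were other overlap rules, autosomes only, parts of the ZT10 list, other windows and draws matched on position.

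Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures matplotlib 3.10.9. The routines were tested on simulated data built on the 11767 real peak positions. All 3579 planted overlaps and 300 of 300 planted shared points were recovered, with 0 points that had not been planted. The planted overlaps were copies of real peaks and the planted distances were exact. These recoveries therefore check the code and give no error rate for the real lists. Among 40 sets drawn without order, 2 were called at a threshold of 0.05. Overlap counts matched those of bedtools 2.31.1 on a list with every peak moved, 67 in both.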

Results

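Rev-erbα, a nuclear receptor that represses transcription and belongs to the circadian clock, was mapped by ChIP-seq in mouse liver at ZT10, near the end of the light phase. The stated design compared 3 wild-type livers with 3 livers lacking HNF6, a hepatocyte transcription factor of the Onecut family. The data analysed here were 2 lists of binding sites. The first was for the pooled ZT10 experiment, the second for sites named as independent of the DNA-binding domain (DBD) of Rev-erbα. No sample was labelled as having an altered DBD. The name of the second list could therefore not be checked with these samples, and DBD-independent below is that name only. The ZT10 list held 11767 peaks and the DBD-independent list 3579, and every peak was 150 bp wide. Neither list held a value for a single liver, so binding in wild-type and HNF6 KO livers was not compared, and depth per sample is unknown.

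The first question was how the DBD-independent sites relate to all Rev-erbα sites. All 3579 DBD-independent peaks were present in the ZT10 list with identical start and end, and they made up 30.4% of it (95% Wilson interval 29.6 to 31.3%). The remaining 8188 peaks, 69.6%, were in the ZT10 list alone. The DBD-independent list was thus a subset of the ZT10 list, and the overlap itself was not open to a test. The share of DBD-independent peaks differed little between chromosomes. It was highest on chromosome 8, with 204 of 615 peaks (33.2%, 29.6 to 37.0%), and among autosomes lowest on chromosome 19, with 121 of 441 peaks (27.4%, 23.5 to 31.8%). On the X chromosome it was 58 of 206 peaks (28.2%, 22.5 to 34.7%). Of 21 chromosomes tested with Fisher's exact test, 0 differed from the rest at an unadjusted p under 0.05, and the smallest adjusted p was 0.737.

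DBD-independent sites were concentrated among the peaks at the head of the ZT10 list. With the list divided into 10 bins of equal size in its own order, 49.3% of the first bin were DBD-independent (580 of 1177 peaks, 46.4 to 52.1%), against 10.5% of the last bin (124 of 1176 peaks, 8.92 to 12.4%). The ratio of the shares was 4.67 (Fisher's exact test, p = 5.2e-99), and the share was lower in each bin than in the bin before it. The median position was 4114 for DBD-independent peaks and 6744.5 for the others, a difference of -2630.5 positions (permutation p = 1e-05, the smallest that 100000 resamples can give). Within the first 5883 peaks of the list alone the difference was -608.5 positions (permutation p = 0.0001, the smallest that 10000 resamples can give). The ZT10 list carries no score, but for the DBD-independent peaks its order followed the 2 values deposited with them. Across these peaks, which are not independent replicates, Spearman's rho with position was -0.94 for the first value and -0.91 for the second (permutation p = 0.0001 for each, the smallest that 10000 resamples can give). The 2 values also followed each other (Spearman's rho 0.94), so the 2 correlations are not separate evidence. The 8188 other peaks carry no such value. The median first value was 30.0 for the DBD-independent peaks of the first bin and 4.0 for those of the last. If the list was chosen by a limit on the ratio of the 2 values, counting noise could have dropped peaks of low value. That technical explanation of the fall stays open, as described under the other observations.

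**Figure D1:**
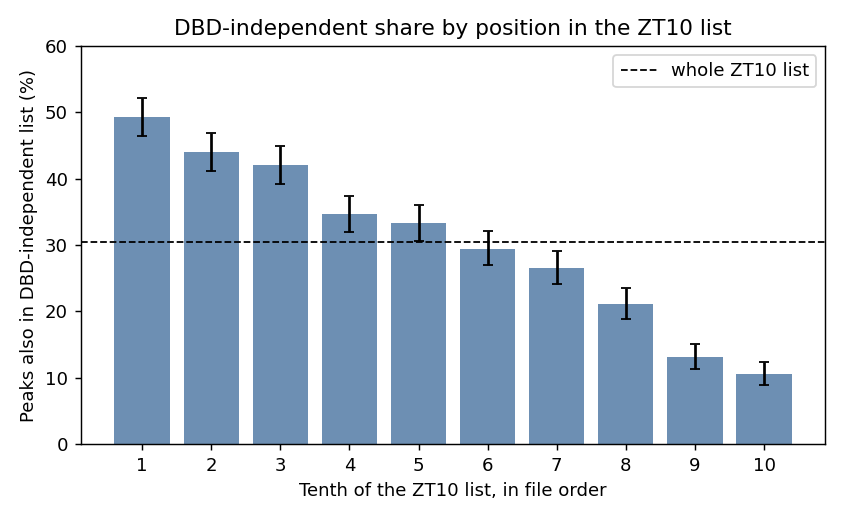
Share of ZT10 peaks that are also in the DBD-independent list (vertical axis, percent) for each of 10 equal bins of the ZT10 list in file order (horizontal axis), with 95% Wilson intervals as error bars and the share in the whole list as a dashed line. The share is 49.3% in the first bin and 10.5% in the last.

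The 5 DBD-independent peaks with the highest first values all stood among the first 7 positions of the ZT10 list. The highest, on chromosome 9 at 58429856 to 58430005, had a first value of 103 and a second value of 80, and lay upstream of its point at a distance of -117 bp. The next, on chromosome 11 at 98634293 to 98634442, had values of 96 and 82 at a distance of 2189 bp. The peak at position 1 of the list, on chromosome 7 at 16683711 to 16683860, had values of 94 and 102 at a distance of -207 bp. The peaks on chromosome 6 at 30516046 to 30516195 (93 and 63, distance -2256 bp) and on chromosome 4 at 129419682 to 129419831 (89 and 72, distance -209 bp) followed. The first ZT10 peak outside the DBD-independent list, on chromosome 1 at 177538268 to 177538417, stood at position 6 and is named although the rule did not ask for it. Genes at these sites are not named because no mm9 annotation was used here.

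Where DBD-independent sites lie relative to genes was described from the deposited distances. These distances behaved as distances to shared, stranded points such as TSSs. In 50 of 54 neighbouring pairs of peaks up to 1000 bp apart (92.6%) the distances differed by exactly the spacing of the peaks, and in pairs 50 to 200 kb apart this held for 84 of 923 (9.10%). Of the DBD-independent peaks, 30.0% (1073 peaks, 28.5 to 31.5%) lay within 1 kb of their point, 25.2% (903 peaks, 23.8 to 26.7%) within 500 bp, and 47.2% (1690 peaks, 45.6 to 48.9%) beyond 10 kb. The median absolute distance was 8.70 kb. The largest was 99816 bp, so that no DBD-independent peak lay beyond 100 kb. Distances of the other ZT10 peaks were not analysed here, so these shares have no comparison group.

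Sites within 500 bp of their point lay mostly upstream and sites farther out more often downstream. Within 500 bp of the point 76.1% of peaks were upstream (687 of 903, 73.2 to 78.8%), against 42.4% beyond 1 kb (1062 of 2506, 40.5 to 44.3%), a difference with an odds ratio of 4.33 (Fisher's exact test, p = 4.6e-70). Between 500 and 1000 bp the upstream share was 41.2% (70 of 170, 34.1 to 48.7%), so the excess was found within 500 bp and not in this interval. It is an excess over DBD-independent peaks farther out. Whether other ZT10 peaks show it too is unknown, because their distances were not analysed here. Within 100 bp of the point, 312 of 415 peaks (75.2%, 70.8 to 79.1%) were upstream. The median first value was 13 within 100 bp and 13 between 50 and 100 kb, and its Spearman's rho with absolute distance, -0.02 across peaks, was not past the threshold (permutation p = 0.134).

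**Figure D2:**
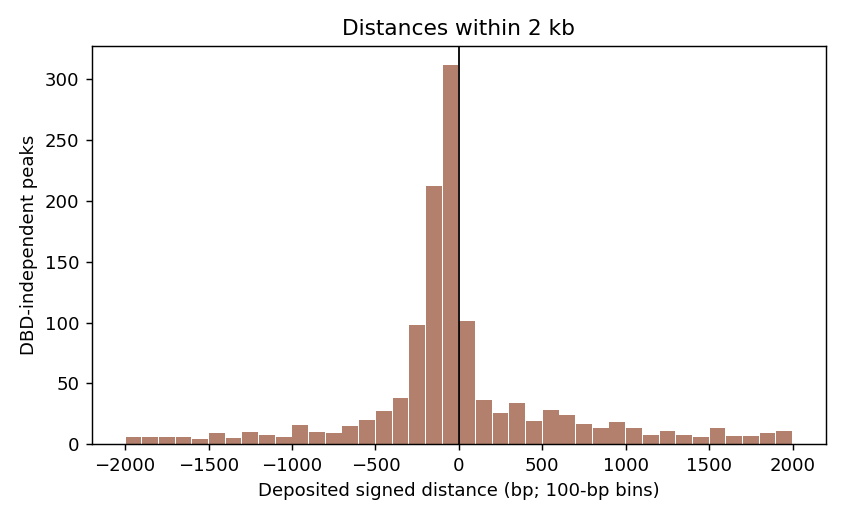
Number of DBD-independent peaks (vertical axis) by deposited signed distance in bins of 100 bp (horizontal axis, bp, negative is upstream), within 2 kb of the point, which the vertical line marks. The bin just upstream holds 312 peaks and the bin just downstream 101.

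Many points were shared by several DBD-independent sites. Exactly 472 positions were shared by at least 2 peaks, 224 on the plus and 248 on the minus strand, and they took in 1037 of the peaks (29.0%, 27.5 to 30.5%). Whether other ZT10 peaks share points as often is unknown, because their distances were not analysed here. Of the 472 points, 395 had 2 peaks, 63 had 3, 13 had 4 and 1 had 6. The points described next were chosen after their values were seen: the point with 6 peaks and, of the 13 with 4, the 3 with the highest first value. The point with 6 peaks, on the minus strand of chromosome 2 at 147872706, had 1 upstream peak at a distance of -148 bp, with first and second values of 32 and 28. Its other 5 peaks lay between 612 and 85220 bp downstream, and 0 other ZT10 peaks fell in the 85.5 kb spanned. On the plus strand of chromosome 10 at 98725866, 4 peaks lay between -29179 and 90840 bp, with a highest first value of 54, and the 120.2 kb spanned also held 3 other ZT10 peaks. On the plus strand of chromosome 4 at 102242666, 4 peaks lay between -76424 and 7783 bp, and the highest first value was 62, at position 51 of the ZT10 list. On the minus strand of chromosome 5 at 87521581, 4 peaks lay between -24 and 11724 bp, with a highest first value of 52, and 0 other ZT10 peaks fell in the 11.9 kb spanned.

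DBD-independent sites lay closer together than equally many sites drawn from the ZT10 list. Of the DBD-independent peaks 13.6% (487 peaks, 12.5 to 14.8%) had another such peak within 10 kb, against 11.1 ± 0.677% (SD) in 10000 random draws (permutation p = 0.0006). This difference of 2.56 percentage points was not seen against draws matched on position in the ZT10 list, which gave 13.5 ± 0.714% (permutation p = 0.855). Of all ZT10 peaks 31.0%, and of those outside the DBD-independent list 22.1%, had a neighbour of their own list within 10 kb, but these lists are longer and the shares are not comparable across lengths.

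Runs of sites within a class were short. The 3 windows chosen for DBD-independent peaks held 4 each, as did 1 further window. They lay on chromosome 2 from 147856006 to 147872928, at the point with 6 peaks, on chromosome 5 from 87509782 to 87521679, and on chromosome 11 from 101565497 to 101577030. In each of these windows all 4 ZT10 peaks were DBD-independent. Among peaks outside the list, the longest run held 7, on chromosome 8 from 87220847 to 87253976, where 1 of 8 ZT10 peaks was DBD-independent. The next windows, on chromosome 5 from 120119053 to 120136342 and on chromosome 11 from 100242972 to 100256783, held 5 peaks each, of which 0 were DBD-independent. All windows were picked for having the most peaks of their class, and the classes differ in size (3579 and 8188 peaks). Run lengths and make-up of the windows are therefore no comparison of the classes.

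The 2 values deposited with each DBD-independent peak never differed by more than 1.5-fold. Their ratios ended just inside this limit on both sides, and if the list was chosen by such a limit, the closeness of the values and their correlation follow from it. The first had a median of 12.0 (range 1.0 to 103.0) and the second a median of 11 (range 1.0 to 102.0), with a Spearman's rho of 0.94 across peaks. The ratio of the second to the first ran from 0.671 to 1.47 with a median of 0.889, and 0 of 3579 peaks lay outside 1.5-fold. The second value was below the first at 60.5% of peaks (2165 peaks, 58.9 to 62.1%), equal at 14.1% (503 peaks) and above it at 25.5% (911 peaks, 24.1 to 26.9%). What the values measure is not stated, including whether they are normalized tag counts of different experiments, so neither can be assigned to a genotype or an experiment.

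**Figure D3:**
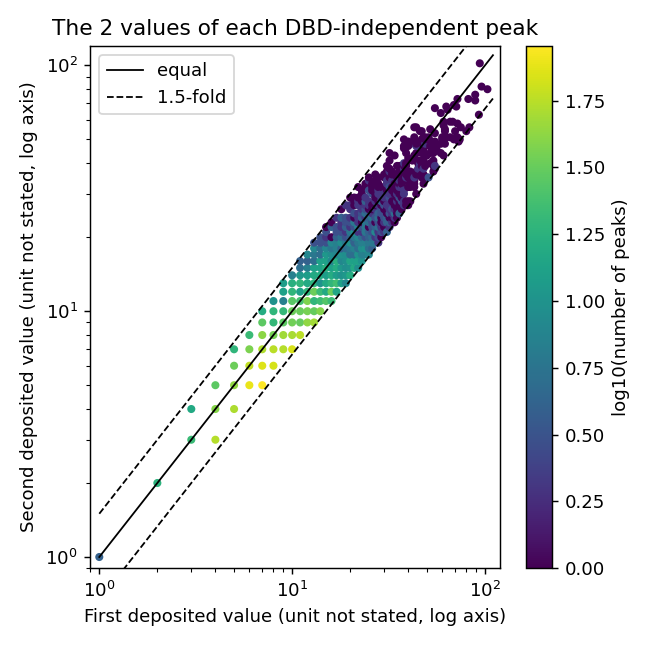
Second against first deposited value of the DBD-independent peaks (both axes logarithmic, unit not stated); each point is a pair of values, coloured by the log10 of the number of peaks that have it. The solid line marks equal values and the dashed lines a 1.5-fold difference, which 0 peaks exceed.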

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

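Of 21 alternatives to 8 results, 15 kept the direction and call, or stayed within the interval or SD, 5 moved a value and 1 ended a call. Planned before the data were examined were the overlap rules and autosomes for the overlap, the 2500 bp window and the 5 and 50 kb windows. The others were chosen after seeing the data. Overlap rules of 50% of the shorter peak or centres within 100 bp changed no membership, since starts in the ZT10 list are at least 154 bp apart. The position test with the centre rule therefore repeated the main result, and these matches are no sign of robustness. For the ratio of the 2 values the SD, 0.192, was the spread over peaks and not the error of a median. The DBD-independent share was 40.7% among the first 5883 peaks of the ZT10 list. The share of DBD-independent peaks near their point was 35.5% within 2500 bp, and a wider window cannot hold fewer peaks. Within 1 kb it was 31.8% for peaks with ordered identifiers and 20.9% for those with unordered identifiers. The upstream share was 70.6% within 1 kb. The excess clustering of 2.56 percentage points was 2.27 at 5 kb and 2.18 at 50 kb, and 0.135 against draws matched on position (permutation p = 0.855). The cause was not tested beyond this matching. The difference in median position kept its direction and call among the first 5883 peaks, but was -608.5 against -2630.5 positions. The range of positions there is smaller by construction. The ratio of first to last shares was 3.95 with 5 bins in place of 10. A stricter peak threshold by score was not run, as the ZT10 list holds no score. No paired analysis was possible because the lists hold no value per replicate. For the same reason no replicate could be left out, and no result here says anything about differences between livers.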

Other observations

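The tests in this part were chosen after the lists had been examined. Some outcomes had not been seen when their tests were set. These were the tests on sites near a known point, on the density along the identifiers and on matched draws. For sites near a known point this holds only with the anchors described below left out. No prediction was set for the version with anchors kept. Outcomes on the spread of the ratios and on the order of the identifiers had been seen in part. Sites at the end of the ZT10 list were seldom DBD-independent also where a TSS-like point was close by. The 1073 DBD-independent peaks within 1 kb of their point served as anchors and were left out, which lowers the DBD-independent shares that follow. Among 1079 ZT10 peaks within 50 kb of an anchor, 40.3% of those in the first of 5 equal bins of the ZT10 list were DBD-independent (83 of 206, 33.8 to 47.1%), against 10.6% in the last bin (25 of 236, 7.28 to 15.2%). With anchors kept, and every peak taken that had an anchor other than itself within 50 kb (1237 peaks), the shares were 50.4% (125 of 248, 44.2 to 56.6%) and 12.8% (31 of 242, 9.17 to 17.6%).

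The fall of the DBD-independent share down the ZT10 list has 2 candidate technical explanations. The first is that the DBD-independent list stops at 100 kb and peaks farther down the ZT10 list may lie farther out. It predicts little fall among sites known to lie within 51 kb of a point. There the ratio of the shares of the first and last of 5 bins was 3.80 without the anchors (95% interval 2.63 to 6.09). With the anchors kept the ratio was 3.94 (2.83 to 5.86), so this explanation is not the whole cause. Both intervals came from binomial draws at the observed shares. Such draws treat peaks as independent, although several can lie near the same anchor, so the intervals may be too narrow. The second is that a limit on the ratio of 2 small numbers would drop peaks of low value through counting noise. The SD of the log2 ratio was 0.267 in the first and 0.273 in the last bin, a difference of 0.00611 (bootstrap 95% interval -0.0134 to 0.0243). The interval includes 0, but this SD cannot decide the question. It covers only peaks that stayed in the list, and the limit itself narrows every SD. This explanation therefore stays open. No biological explanation was tested, since the lists separate no genotypes.

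The excess clustering of DBD-independent peaks may come from their place in the ZT10 list, whose order follows strength only as far as the listed peaks show. The excess over random draws was 2.56 percentage points without matching and 0.135 with draws matched on 10 bins of the ZT10 list. A range of 12.1 to 14.9% took in the central 95% of matched draws, and the observed 13.6% lay inside it.

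The identifiers of the DBD-independent peaks carry a structure that the file does not explain. For 2982 peaks, with identifiers from 1814 to 25915, distances fell without exception from 99816 to -99629 bp as the identifiers rose, with 0 rises among 2981 consecutive pairs. For the other 597 peaks, with identifiers from 27179 to 41075, 313 of 596 consecutive pairs rose. A candidate explanation is that the identifiers below 27000 are row numbers of a larger table sorted by distance to TSS. The peaks with unordered identifiers had a median first value of 10 against 13, and stood farther down the ZT10 list (median position 6058 against 3652.5, permutation p = 0.0001, the smallest that 10000 resamples can give). They lay within 1 kb of their point at 20.9% (125 peaks, 17.9 to 24.4%) against 31.8% (948 peaks, 30.1 to 33.5%; Fisher's exact test, p = 6.7e-08).

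If the ordered identifiers are such row numbers, they also say how the unseen rows were distributed. Between 6267 and 6285 of the 24102 rows spanned would then lie within 1 kb of a TSS. DBD-independent peaks would be 948 of at most 6285 such rows (15.1%, 14.2 to 16.0%) and 2034 of the remaining 17817 (11.4%, 10.96 to 11.9%), an odds ratio of 1.38 (Fisher's exact test, p = 9.16e-14). Among these rows, DBD-independent peaks would be modestly over-represented near TSSs. This is a hypothesis that rests on reading the identifiers as row numbers and on a table whose content is unknown. The ZT10 list holds 11767 peaks, so not every one of the 24102 rows can be a separate ZT10 peak. Whether ZT10 peaks in general show the same difference is therefore unknown. The 597 peaks with unordered identifiers were left out. Of these, 20.9% lay within 1 kb of their point, against 26.1% of the rows at most. The comparison also leaves open whether position in the ZT10 list or the choice of the list produced the difference.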
